A study of Mus musculus with 2 samples.

How the data were processed

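Whole uteri of pregnant mice were collected on gestational day 4 and total RNA was sequenced from 1 library labelled Mettl3 f/f and 1 labelled Mettl3 ed/ed. The labels do not say how many animals each library holds, nor what the letters of the genotypes stand for. Libraries were made with an Illumina TruSeq RNA kit from RNA extracted with TRIzol, per the labels' protocols. Whether the kit kept strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

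The deposited tables hold 1 value per gene, with Ensembl gene identifier and symbol. The values were taken as FPKM, that is fragments normalised to transcript length and to the number of mapped fragments, made by the authors with Cufflinks 2.2.1 after alignment with HISAT2 2.2.1, both named in the submitters' processing notes. The unit is an inference from Cufflinks, which writes FPKM, and from the values, which are decimals with exact zeros and sums that differ between libraries, since the header names no unit. The submitters' processing notes name the mouse builds mm9 and mm10 without saying which was used. The annotation, filters and multi-read settings are not given in the sources used here. FPKM divides by transcript length and total fragments, so a few very abundant genes, RNA quality or a difference in how long transcripts were captured can move many values together. An exact 0 can be an estimate that failed, so such genes are said to be listed at 0 and given no fold. Of the ribosome and reference genes listed, 0 were at 0 in either library.

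Depth was estimated because FPKM keeps no total. In genes with 1 annotated transcript longer than 1000 nt, low values of a library fall on multiples of the value of 1 fragment. Each value was multiplied by the effective length in kilobases, taken as 250 nt shorter than the transcript. The spacing of these products was 0.0547 in f/f (concentration 0.377 in 315 genes, against at most 0.191 in 100 shuffles of the lengths). It was 0.0576 in ed/ed (0.406 in 326 genes, against at most 0.185). The offset is an assumption and the estimate covers counting error only.

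Values were compared as log2 of (ed/ed FPKM + 1) over (f/f FPKM + 1), among the 12165 genes at 1 FPKM or more in either library. Every fold is on that scale, which understates differences of low genes. A gene was called higher or lower at 2-fold, a rule of size that stands in for a test because each genotype has 1 library. No p-value or SE was made, since genes are not replicates. There were 0 repeated symbols.

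Before the data were examined, 42 gene lists were fixed from textbook knowledge, with 896 entries, of which 856 were matched by symbol. They cover m6A machinery, hormone response and receptivity, cell types of the uterus and of neighbouring tissues, cell cycle, stress, signalling, secretion, matrix, imprinting and signs of RNA quality. For each list the median log2 ratio of expressed members was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. Of the lists, 40 had at least 3 expressed members. Histone and mitochondrial genome genes had 0 members matched and, like the writer complex gene Virma, are not analysed here.

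Genes named in the text followed a rule fixed at the same time. It took the m6A writer complex, the 12 highest and 12 lowest ratios among expressed genes and the 6 highest and 6 lowest among genes with a mean of at least 20 FPKM, leaving out clone-type symbols. It also took up to 4 members with the largest absolute ratio in each list described, and Actb and Gapdh. Other genes are said to be chosen after their values were seen.

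Coordinates, transcript lengths and GC content came from GENCODE M21 on GRCm38, matched on Ensembl identifier for 20557 genes, of which 20536 had the same symbol. Length is that of the longest coding transcript and was found for 99.94% of the genes compared. Since the build behind the deposited values is open, these coordinates locate genes and not reads. The length trend was removed by lowess (fraction 0.3) of the log2 ratio on log2 length, and GC content in the same way afterwards. Removing the length trend also took out the overall offset between the libraries, the median log2 ratio of -0.26 over all genes. Changes seen without the length trend are therefore not due to length alone. Intervals of list medians are 95% bootstrap intervals from 10000 draws of members, which cover the spread across genes and not between animals.

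Alternatives set beforehand were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at 5 FPKM, a 1.5-fold rule, lists without members held by another list, and 4 scalings. The scalings used the sum, the median ratio, the upper quartile or the reference genes of each library. Scaling by the sum set each library to a common total above both deposited sums, so the pseudocount and filter weighed less. Removal of length and GC trends, random lists matched on length, and ed/ed brought to the sum of f/f with the pseudocount and filter as deposited were added after the data were seen. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.

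The procedure was tested on simulated data made from the mean of both libraries, with noise of SD 0.2 log2 in each simulated library and 200 genes at a mean of 5 FPKM or more altered among 11805. The 2-fold rule called 2.0% of simulated 1.5-fold differences, 44.0% of 2-fold, 94.0% of 3-fold and 100.0% of 4-fold, and 0.0173% of 11583 unaltered genes. These rates follow from the chosen noise, since no offset, counting noise or difference between animals was put in. The real log2 ratios had an SD of 0.58 and a median of -0.26, so the rates are not error rates of these libraries. A list lowered by 0.8 came out at percentile 0.0, and 40 unaltered lists had a median percentile of 64.7, above the middle of the random lists. A length trend put into 11576 genes had a rho of -0.522 before and -0.003 after removal.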

Results

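RNA-seq profiles of whole mouse uterus on gestational day 4 were compared between 2 libraries, 1 labelled Mettl3 f/f and 1 labelled Mettl3 ed/ed. Pregnancy was counted from the vaginal plug as day 1, and the uterus was taken whole, so each library mixed epithelium, stroma, muscle, vessels and immune cells. Mettl3 encodes the catalytic subunit of the methyltransferase complex that writes N6-methyladenosine (m6A) on RNA. The comparison asked which genes differed in expression between the uteri of both genotypes. With 1 library per genotype there was no replicate check, so each difference below is between these 2 libraries, and no spread between animals could be estimated.

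Both libraries listed the same 20634 genes, with 11876 at 1 FPKM or more in the f/f library and 11563 in the ed/ed library. Depth was estimated from the spacing of low values at 18300000 fragments for f/f and 17400000 for ed/ed. At that depth a transcript of 2000 nt at 1 FPKM corresponded to 32 and 30 fragments. The listed values summed to 522049 and 491403 FPKM, and the 10 most abundant genes held 10.2% and 11.95% of these sums. The most abundant genes were Ctsd at 7228 FPKM in f/f, which encodes the lysosomal protease cathepsin D, and Rpl41 at 8075 FPKM in ed/ed, a ribosomal protein gene.

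Mettl3 (ENSMUSG00000022160, chromosome 14, positions 52294841 to 52305128, GRCm38) was at 10.6 FPKM in the library labelled f/f and 10.2 FPKM in the library labelled ed/ed. Its log2 ratio of -0.05 changed sign under each of the 4 other scalings, from 0.03 to 0.28. The estimated fragments behind these values were 344 and 315, and the ratio of 0.963 had a counting interval of 0.824 to 1.13. The transcript level of the targeted gene therefore did not separate the libraries, and the directions below rest on their labels, for which f/f and ed/ed stand throughout. A value summed over the whole gene can stay the same where only some exons are missing. The other expressed members of the m6A writer complex also lay within 2-fold. Mettl14, the partner of Mettl3, was at 11.9 and 12.2 FPKM, Wtap at 33.9 and 36.4, Cbll1 at 7.82 and 7.94, and Rbm15 at 3.41 and 4.23. Zc3h13 was at 7.95 and 6.01 FPKM and Rbm15b at 10.9 and 8.55, the latter lower under 3 of the 4 other scalings. Over the 7 members the median log2 ratio was 0.02 and the mean -0.05. Of 11 expressed m6A erasers and readers, 0 differed 2-fold, and their median of -0.04 turned positive under all 4 other scalings.

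Most expressed members of the stromal, vascular, matrix, progesterone-response and mitotic lists had lower FPKM in the library labelled ed/ed than in that labelled f/f. Most expressed members of the interferon-response and secreted defence lists had higher FPKM in ed/ed. Collagen IV, fibronectin and the endothelial cadherin Cdh5 were among the lower genes, whereas Isg15, Oas2, Pigr and complement C3 were among the higher. The lowest ratio belonged to Cbr2, a carbonyl reductase, at 289 FPKM in f/f and 8.52 in ed/ed. The highest with a value above 0 in both belonged to C1qtnf9, a secreted protein with a C1q domain, at 1.82 and 66.7 FPKM. Of 12165 genes at 1 FPKM or more in either library, 326 were at least 2-fold higher in ed/ed, 757 were at least 2-fold lower, and 11082 (91.1%) lay within 2-fold, on the scale of log2(FPKM + 1).

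**Figure D1:**
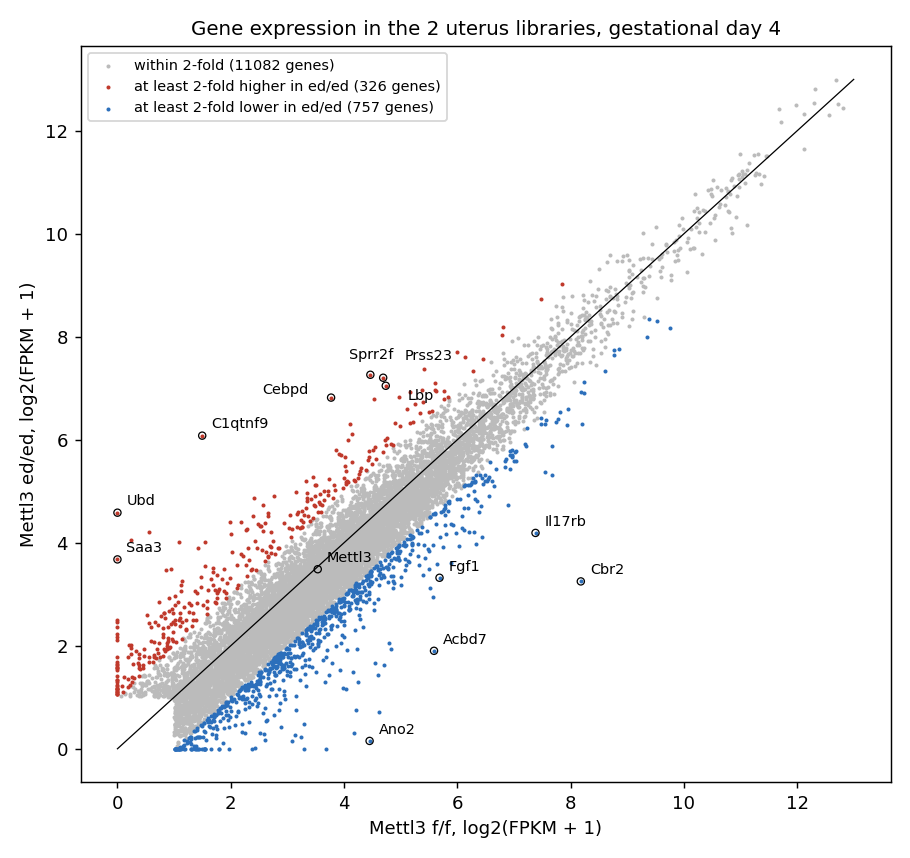
Each point is 1 of 12165 genes, with log2(FPKM + 1) in the f/f library on the horizontal axis and in the ed/ed library on the vertical axis. The line marks equal values, red points are the 326 genes at least 2-fold higher in ed/ed, blue points the 757 at least 2-fold lower, and Mettl3 lies next to the line.

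The balance of higher and lower genes depended on the scale. As deposited, the median log2 ratio over all 12165 genes was -0.26 (SD 0.58 across genes), and 30.1% of the genes that differed 2-fold were higher in ed/ed. Relative to that median, 603 genes were higher and 331 lower (64.6% higher). The other scalings shifted the log2 ratio by 0.09 (sum of each library), 0.21 (upper quartile), 0.29 (median ratio) and 0.36 (reference genes). They gave 551 higher and 914 lower (37.6% higher), 487 and 442 (52.4%), 572 and 359 (61.4%), and 645 and 308 (67.7%). The sum scaling set both libraries to a larger common total, so a pseudocount and filter of 1 weighed less and 13001 genes entered, and its counts are not due to the shift alone. With ed/ed brought to the sum of f/f and all else as deposited, an alternative chosen after the data were seen, 387 genes were higher and 608 lower. Medians of gene lists are therefore also given as the difference from the median of all genes. Ratios also followed transcript length, with a Spearman rho of -0.22 across 12158 genes, which are not independent replicates. The median log2 ratio was -0.01 in the shortest of 10 equal groups of genes by transcript length and -0.43 in the longest. With the length trend removed, a correction chosen after the data were seen, 526 genes were higher and 347 lower (60.3% higher). Of these, 324 and 346 were also called on the deposited scale. That correction also centres the ratios near 0, so its counts compare with the 603 and 331 relative to the median of all genes.

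**Figure D2:**
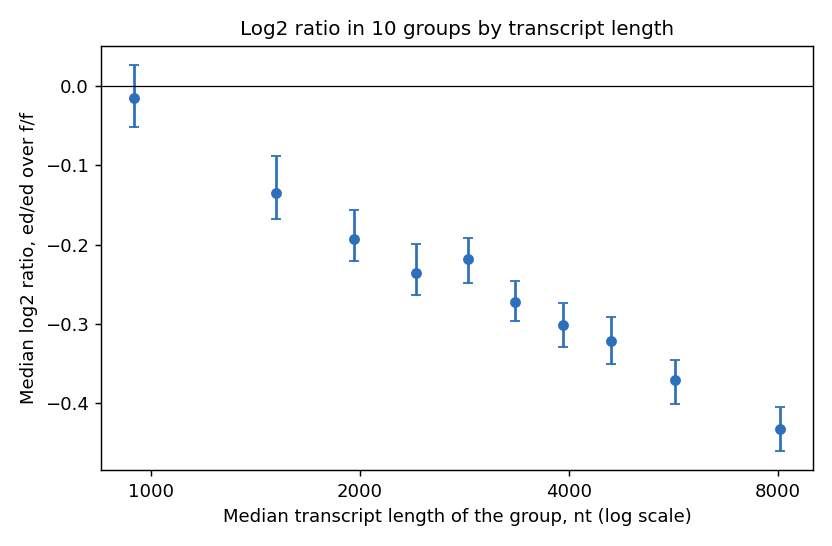
Points are the median log2 ratio of ed/ed over f/f in each of 10 equal groups of genes by transcript length, plotted at the median length of the group in nucleotides on a log axis, with bars for the 95% bootstrap interval over genes. The median lies at -0.01 for transcripts near 946 nt and at -0.43 for those near 8068 nt.

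The genes with the highest ratios, named by the fixed rule and not tested for a shared function, were as follows. Ubd, which encodes the ubiquitin-like protein FAT10 (chromosome 17, 37193892 to 37196095), was listed at 0 in f/f and was at 23.0 FPKM in ed/ed. Saa3, an acute-phase serum amyloid gene, was listed at 0 and at 11.8 FPKM. The transcription factor gene Cebpd (chromosome 16, 15887286 to 15891031) was 8.27-fold higher, at 12.7 and 112 FPKM. Sftpd, which encodes the collectin surfactant protein D, was at 1.11 and 15.2 FPKM. Lbp, the lipopolysaccharide-binding protein gene, was at 25.7 and 132 FPKM, and the chemokine gene Cxcl17 at 22.02 and 110 FPKM. C1qtnf9 (chromosome 14, 60768134 to 60780869) was 24.0-fold higher. The serine protease genes Htra4 and Prss23 were at 0.477 and 17.4 and at 24.9 and 147 FPKM. Sprr2f, an estrogen-induced small proline-rich protein gene, was 6.96-fold higher, at 21.1 and 153 FPKM, and shares sequence with other Sprr2 genes, so that its reads are uncertain. Sval2, Tmem213 and Fbxo36 were at 0.185 and 15.6, 0.820 and 10.1, and 0.934 and 10.2 FPKM, and Gtf2a1l was listed at 0 and at 4.67 FPKM.

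The genes with the lowest ratios were named in the same way. Cbr2 (chromosome 11, 120729489 to 120732114) was 30.5-fold lower in ed/ed. The calcium-activated chloride channel gene Ano2 (chromosome 6, 125690419 to 126040126) was at 20.9 FPKM in f/f and 0.111 in ed/ed, and the sodium/iodide symporter gene Slc5a5 at 23.5 and 0.634. Kcnc4, a voltage-gated potassium channel gene, was at 8.44 and 0.168 FPKM, and the dopamine receptor gene Drd4 at 17.4 and 0.687. Il17rb, a receptor subunit for interleukin-25, was 9.12-fold lower, at 166 and 17.3 FPKM. Nptx1 was at 17.0 and 0.240 FPKM, Acbd7 at 47.2 and 2.74, Spink8 at 23.2 and 1.70, and Wfdc13 at 24.96 and 2.08. Wfdc15b and Ly6f were at 11.8 and 8.86 FPKM in f/f and listed at 0 in ed/ed. Among abundant genes, Plb1 was at 46.6 and 6.69 FPKM, Slc51a, an organic solute transporter gene, at 44.6 and 7.66, and Fgf1 at 50.5 and 8.99. Of 3571 genes with a mean of at least 20 FPKM, 82 were higher and 168 lower by 2-fold. Of the reference genes, Actb was at 964 and 1154 FPKM, and Gapdh, which has many pseudogene copies, at 19.1 and 18.3 with a sign that changed under all 4 other scalings.

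Genes of stroma and vessels were lower as groups. Of 22 stroma genes, 6 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.80 (difference from all genes -0.54). None of 10000 random lists matched on expression had a median as low. Pdgfra, the platelet-derived growth factor receptor of fibroblasts, was at 28.0 FPKM in f/f and 9.30 in ed/ed, Col6a1 at 131 and 47.3, Col3a1 at 247 and 96.4, and Col1a1 at 78.6 and 35.6. All 13 expressed endothelial genes lay below the median of all genes and 7 were 2-fold lower, with a median of -1.07 (difference -0.81) and 0 of 10000 random lists as low. Cdh5 (chromosome 8, 104101625 to 104144511) was at 42.0 and 12.01 FPKM, the angiopoietin receptor gene Tek at 7.92 and 1.93, Tie1 at 19.6 and 7.44, and Eng at 29.2 and 11.8. Of 30 extracellular matrix and protease genes, 18 were lower and 0 higher, with a median of -1.07 (difference -0.81) and 0 random lists as low. The matrix list shares 5 expressed genes with the stroma list, so these lists are not independent. The basement membrane collagen genes Col4a1 (chromosome 8, 11198423 to 11312826) and Col4a2 (chromosome 8, 11312805 to 11449287), which lie head to head, were at 84.9 and 25.4 FPKM and at 51.0 and 16.2 FPKM. Fibronectin gene Fn1 was at 59.4 and 19.4 FPKM, and the protease inhibitor gene Timp3 at 41.4 and 14.5. With the length trend removed, which also centres the ratios near 0, the medians were -0.54, -0.81 and -0.73 for stroma, endothelium and matrix. The genes at least 2-fold lower then numbered 2 of stroma, 2 of endothelium and 5 of matrix.

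Of 16 myometrium genes, 15 lay above the median of all genes, and the list median was 0.40 (difference 0.66; 95% bootstrap interval 0.31 to 0.67), at percentile 99.99 of random lists. Only Cnn1 (calponin) passed 2-fold, against 3 genes without the length trend, at 48.2 and 122 FPKM, whereas Actg2 was at 68.8 and 136, Tagln at 133 and 251, and Tpm2 at 69.3 and 116. Epithelium genes had a median of 0.14 over 23 members, at percentile 99.76, but its 95% bootstrap interval of -0.41 to 0.50 spanned both 0 and the median of all genes. Of the members 1 was higher and 1 lower (4 and 1 without the length trend), and 10 lay below the median of all genes. Cldn7 was at 232 and 437 FPKM and St14 at 51.4 and 100.03, while Rab25 was at 53.8 and 22.3. Luminal epithelium genes had a median of 0.44 over 10 members (2 higher, 1 lower; percentile 99.95; interval -0.68 to 1.23; 3 higher and 0 lower without the length trend), with Vtcn1 at 14.4 and 51.3 FPKM and Cd44 at 21.1 and 9.79. Glandular epithelium genes had a median of 0.30 over 11 members (3 higher, 1 lower; percentile 99.65; interval -0.46 to 1.15). Foxa2, a transcription factor required for uterine glands, was at 0.924 and 4.40 FPKM, Sox9 at 0.387 and 2.83, Spink1 at 15.7 and 35.96, and Guca2b at 1.63 and 0.175.

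**Figure D3:**
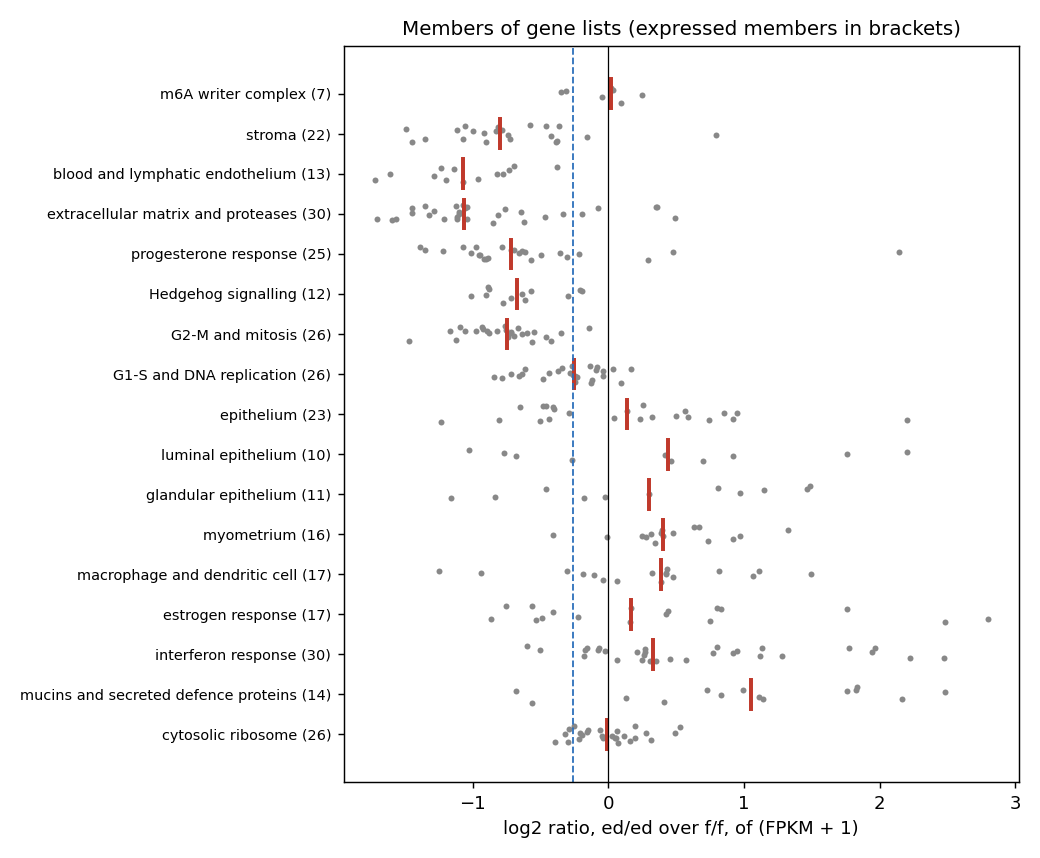
Grey points are the expressed members of 17 gene lists, placed by the log2 ratio of ed/ed over f/f of FPKM + 1, and red bars are list medians. The dashed blue line is the median of all genes (-0.26) and the black line is 0, and the medians of stroma, endothelium and matrix lie left of the dashed line, with those of myometrium, interferon and defence genes right of 0 under each scaling used; those of m6A writers and ribosome lie near 0, and the ribosome median turns positive under all 4 other scalings.

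Of 25 progesterone-response genes, 5 were 2-fold lower and 1 higher, with a median of -0.72 (difference -0.46) and 0 of 10000 random lists as low. Without the length trend 3 were lower and 1 higher. Hdc, the histidine decarboxylase gene, was at 653 FPKM in f/f and 254 in ed/ed, Hsd11b2 at 121 and 51.3, and Il13ra2 at 15.9 and 5.47. Cyp26a1, which encodes a retinoic acid hydroxylase of the luminal epithelium, went the other way, at 4.22 and 22.1 FPKM. Hedgehog signalling genes, which carry progesterone signals from epithelium to stroma, had a median of -0.68 over 12 members (difference -0.42, 0 higher, 1 lower, percentile 0.30). Without the length trend their median was -0.34 with 0 lower. The ligand gene Ihh was at 41.0 and 21.7 FPKM, its receptor gene Ptch1 at 23.8 and 11.3, and Nr2f2 at 49.2 and 25.9. Of the 28 progesterone-response genes listed, 15 are also in another list, with 5 shared with Hedgehog signalling and 4 with the stroma list, whose median was also lower (-0.80). Without members held by another list the progesterone median was -0.67 and the Hedgehog median -0.64. Estrogen-response genes had a median of 0.17 over 17 members (3 higher, 0 lower; percentile 99.72), with C3 at 1.67 and 13.9 FPKM, the siderophore-binding lipocalin gene Lcn2 at 2.201 and 9.81, and Txnip at 102 and 55.4. The 95% bootstrap interval of the estrogen median was -0.49 to 0.80, and without members held by another list the median was -0.41, on the same side as that of progesterone-response genes. Once the length trend was removed, 5 estrogen-response genes were higher and 0 lower. The difference between both lists was not tested. Receptivity and implantation genes had a median of -0.06 over 25 members (1 higher, 2 lower; percentile 95.23) that turned positive under all 4 other scalings. Without the length trend the median was 0.32, with 2 higher and 0 lower, and the log2 ratios of Egfr and Ptgs1 were -0.69 and -0.87, within 2-fold. Egfr was at 13.3 and 5.50 FPKM, the cyclooxygenase gene Ptgs1 at 54.0 and 24.7, and Il6st, the shared receptor subunit for leukemia inhibitory factor, at 26.2 and 13.3. Foxa2, also in the glandular epithelium list, was the higher member and had the largest ratio, at 0.924 and 4.40 FPKM. Of the 25 receptivity members, 12 had a log2 ratio above 0 and 13 below. Decidual markers had a median of -0.72 over 11 members (1 higher, 1 lower; percentile 0.17) and 0.35 without members of other lists. Once the length trend was removed, 1 was higher and 0 lower. Hand2, a stromal transcription factor induced by progesterone, was at 40.6 and 18.8 FPKM, and Aoc1 at 0.182 and 2.88.

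Interferon-response genes were higher as a group. Of 30 expressed members, 28 lay above the median of all genes and 8 were at least 2-fold higher, with 0 lower. The list median was 0.33 (difference 0.59), and 0 of 10000 random lists had a median as high. Oas2, a sensor of double-stranded RNA, was at 4.29 FPKM in f/f and 28.4 in ed/ed, and Oasl1 at 3.52 and 20.1. The ubiquitin-like modifier gene Isg15 (chromosome 4, 156199424 to 156200818) was at 41.5 and 164 FPKM, and Ifit1 at 13.5 and 54.7. Macrophage and dendritic cell markers had a median of 0.39 over 17 members (3 higher, 1 lower; percentile 99.99), with a 95% bootstrap interval of -0.10 to 0.47 and 6 members below 0. Aif1 was at 7.27 and 22.3 FPKM and Lyz2 (lysozyme) at 86.6 and 188, whereas Cd14, a co-receptor for lipopolysaccharide, was at 114 and 47.2. Mucins and secreted defence proteins had the highest median of the 40 lists with enough members, 1.05 over 14 members (difference 1.31), with 7 higher, 0 lower and 0 random lists as high. Of its 24 listed genes 8 are in another list, among them C3 and Lcn2 of the estrogen list and Lyz2 of the macrophage list, and the median was 0.99 without these 8. Pigr, the receptor that carries immunoglobulin A across epithelium, was at 14 and 52.1 FPKM, and Wfdc18 at 9.92 and 38.0. Defb1, a defensin gene, was listed at 0 and at 3.48 FPKM. Of the 14 members, 12 had a log2 ratio above 0 and 2 below. These 2 were named after their values were seen. Wfdc2, the most abundant member, was at 1505 and 937 FPKM, and Ltf at 24.4 and 16.2. The higher median therefore does not mean more total RNA of these genes. Inflammatory genes had a median of 0.11 over 16 members (2 higher, 1 lower; percentile 99.16, or 94.48 among random lists matched on length), and -0.03 without members of other lists. In that list Saa3 and Lcn2 were higher and Ccl2, a monocyte chemokine gene, was at 2.69 and 0.324 FPKM.

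Of 26 genes of G2-M and mitosis, 25 lay below the median of all genes and 5 were 2-fold lower, with a median of -0.75 (difference -0.49) and 0 of 10000 random lists as low. Without the length trend, whose removal also centres the ratios near 0, the median was -0.45 and 1 gene was 2-fold lower. Centring alone gives the difference of -0.49, so the move from -0.75 was mostly not due to length. Prc1, a spindle midzone protein gene, was at 19.3 FPKM in f/f and 6.30 in ed/ed, Kif20a at 13.4 and 5.42, Anln at 12.8 and 5.32, and the cyclin gene Ccnb1 at 18.9 and 8.32. The 26 genes of G1-S and DNA replication had a median of -0.25 (difference 0.01; percentile 58.0), with 0 higher and 0 lower and a sign that flipped under 1 scaling. Immediate early genes had a median of 0.31 over 16 members (1 higher, 0 lower; percentile 99.98) and 3 higher without the length trend, with Ier3 at 13.2 and 31.5 FPKM, Jund at 112 and 206, and Fos at 4.78 and 9.57. Genes of the p53 and DNA damage response had a median of -0.50 over 21 members (2 higher, 3 lower; percentile 2.13), with Sesn2 at 14.4 and 3.17 FPKM, Bbc3 at 16.1 and 5.86, and Gadd45a at 8.46 and 20.8. Cytosolic ribosome genes had a median of -0.01 over 26 members and oxidative phosphorylation genes of -0.02 over 24, with 0 members of either past 2-fold, and both medians turned positive under all 4 other scalings. The 20 reference genes had a median of -0.36 (0 higher, 1 lower; percentile 3.48), and the lower one was Polr2a, at 18.1 and 5.02 FPKM.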

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

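The corrections for length and GC, the length-matched lists and ed/ed brought to the sum of f/f were chosen after the data were seen. The cause was not tested for any movement below, except where fewer or more genes entered by construction. The 326 higher genes became 112 with a pseudocount of 5 FPKM, 551, 572 and 645 under the sum (which also lessened the weight of the pseudocount and filter), median ratio and reference gene scalings, 856 at 1.5-fold, 526 without the length trend and 512 without length and GC trends. The 757 lower genes became 1336 and 207 with pseudocounts of 0.1 and 5 FPKM, 359, 442 and 308 under the median ratio, upper quartile and reference gene scalings, 2850 at 1.5-fold, and 347 and 356 without the trends. Mettl3 ranged from -0.05 to 0.28. List medians moved for inflammatory genes at the 5 FPKM filter (0.765), neutrophil (0.544) and mast cell (0.714) genes under the sum, and lymphocyte genes under reference gene scaling (0.681), where rescaling changed which members passed the filter. Without members of other lists, estrogen (-0.412), decidual (0.348) and inflammatory (-0.03) medians reversed. With length-matched lists, receptivity reached percentile 98.5, whereas red blood cell (94.68), inflammatory (94.48) and ion transport (2.9) genes came inside the middle 95% of random lists. Without the length trend, all 40 list medians moved by less than 1.5-fold. Removing a trend also centres the ratios, so movements without the trends are not due to length or GC alone. Of 178 named genes, 41 moved with a pseudocount of 0.1 FPKM, 47 with 5 FPKM and 13 under the sum, and 0 of those past 2-fold changed sign. Symbols were never repeated, so no choice among repeated symbols was needed. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out. Depth limits genes near 1 FPKM, which rest on about 30 fragments for 2000 nt.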

Other observations

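The genes of the WFDC family, secreted proteins with a whey acidic protein domain, were looked at after their values were seen. Of 9 expressed members, 3 were 2-fold higher in the library labelled ed/ed and 5 lower, with a median log2 ratio of -1.30. The 6 members on chromosome 2 held 4 of the lower genes and 1 higher gene. There Wfdc10 was at 44.4 FPKM in f/f and 10.3 in ed/ed, Wfdc6a at 7.51 and 0.110, Wfdc3 at 0.982 and 4.48, and the most abundant, Wfdc2, at 1505 and 937. Both members on chromosome 11, Wfdc17 (8.55 and 18.7 FPKM) and Wfdc18, were higher, and Wfdc1 on chromosome 8 was at 86.2 and 34.4. Of 31 collagens, a family also chosen afterwards like those that follow, 14 were lower and 1 higher, and of 10 laminins 3 were lower and 0 higher. Their medians were -0.91 and -0.93 as deposited, and -0.51 and -0.58 without the length trend. Among 7 Oas and Oasl genes 3 were higher and 0 lower (median 0.95), whereas among 16 Ifi and Ifit genes 2 were higher and 0 lower, with a median of -0.05 (0.08 without the length trend).

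Among lists fixed beforehand, those of transport and metabolism held members that went both ways. Ion and water transport genes had a median of -0.49 over 19 members (difference from all genes -0.23, 1 higher, 4 lower, percentile 2.18, or 2.90 among random lists matched on length). Without the length trend their median was -0.17, with 2 higher and 3 lower. The epithelial sodium channel gene Scnn1a was at 9.01 FPKM in f/f and 1.34 in ed/ed, its regulator kinase gene Sgk1 at 73.2 and 17.6, and the potassium channel subunit gene Kcne3 at 16.7 and 68.6. Retinoid and steroid metabolism genes had a median of -0.31 over 19 members (3 higher, 4 lower; percentile 32.44). Stra6, the retinol transporter gene, was at 68.5 and 17.98 FPKM, Ces1d at 120.5 and 42.3, and Hsd11b1, which regenerates active glucocorticoid, at 1.19 and 8.62. Imprinted genes had a median of -0.54 over 9 members (0 higher, 3 lower; percentile 6.80), with Mest at 58.0 and 11.2 FPKM. Wnt genes had 0 higher and 5 lower of 27 (median -0.31; percentile 31.7), with the antagonist gene Sfrp2 at 56.0 and 23.6 FPKM and Wnt6 at 8.61 and 3.01. FGF and EGF genes had 2 higher and 2 lower of 16 (median -0.23, positive under 2 of the 4 other scalings and without the length trend, where 2 were higher and 1 lower; percentile 63.14). BMP and TGF-beta genes had 0 higher and 1 lower of 23, Bmp7 at 18.3 and 7.86 FPKM (median -0.37, difference from all genes -0.11, percentile 17.6). Without the length trend 0 of them were lower, with a median of -0.07. Prostaglandin genes had 0 higher and 1 lower of 17 (median -0.32; percentile 32.29), and 0 lower with a median of 0.03 without the length trend. Unfolded protein and heat shock genes had 0 higher and 0 lower of 20 (median -0.29, positive under 1 scaling; percentile 22.23).

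Markers of other cells were few. Lymphocyte markers had 1 higher and 0 lower of 8 (median 0.06; percentile 94.47), and their median was 0.681 under reference gene scaling, with Jchain at 5.50 and 14.4 FPKM. Of the 20 macrophage and dendritic cell markers given in the report 1 is in another list, and of the 30 interferon genes 0 are. Neutrophil markers had 1 higher and 1 lower of 6 (median -0.22; percentile 64.46), and mast cell and eosinophil markers 0 higher and 1 lower of 3 (median -0.22; percentile 49.93). Under scaling by the sum, which let more members pass the filter, the medians of these lists turned to 0.544 and 0.714. The lower mast cell gene was Hdc, also in the progesterone-response list, at 653 FPKM in f/f and 254 in ed/ed. The mast cell protease genes Cpa3 and Mcpt4, chosen after their values were seen, were listed at 0 in both libraries. Red blood cell markers had 0 of 5 past 2-fold (median 0.37; percentile 99.04, or 94.68 among random lists matched on length) and adipocyte markers 0 of 3 (median 0.07; percentile 83.7). Ovary and oviduct markers had 0 higher and 3 lower of 7 (median -0.66; percentile 4.57), and 1 higher and 1 lower without the length trend, with Pgf, a placental growth factor gene that other tissues also express, at 7.95 and 1.04 FPKM. Blastocyst markers had 0 of 5 past 2-fold, with a median of -0.16, positive under 1 of the 4 other scalings, and a mean of 0.06 (percentile 65.18). The 5 included Krt8, also in the epithelium list, at 430 and 307 FPKM. Pou5f1, Nanog and Cdx2, chosen after their values were seen, were listed at 0 in both libraries, so the median does not compare blastocyst cells. Without the length trend 1 gene each of the red blood cell, mast cell and blastocyst lists was higher.

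The tests of length and of scaling on the stroma, endothelium and matrix genes were set before their values were computed, although the length correction itself was added after the data were seen, and the other tests in the next paragraphs were chosen only after the results were seen. The 60 expressed genes of the stroma, endothelium and matrix lists had a median log2 ratio of -0.91 (95% bootstrap interval -1.07 to -0.76). Transcript length as the whole cause was argued against, since the median was -0.652 (-0.763 to -0.490) without the length trend, and so was library scaling, since the scaling that brought it nearest to 0, by reference genes, left -0.592 (-0.758 to -0.433). A lower share of stromal cells alone, with the vessels spared, would raise endothelium and myometrium alike. The endothelium median minus that of myometrium was -1.481 (-1.764 to -1.142). Both medians were known when this comparison was chosen, so its outcome was fixed in advance. It does not bear on a joint lower share of stroma and vessels, which was not tested. A lower share of endometrium in the tissue taken, as the whole cause, would lower stroma and epithelium alike. The stroma median minus that of epithelium was -0.79 (-1.301 to -0.318), so these lists did not move alike, but both medians were also known beforehand. As part of the cause a lower share of endometrium remains possible, with epithelium minus myometrium at -0.421 (-0.869 to 0.06). The intervals draw genes within 1 library per genotype. These arguments therefore hold for the listed genes in these libraries, and not for differences in tissue sampling between animals. A biological difference between the genotypes is untested with 1 library each.

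The 30 interferon-response genes had a median 0.586 (95% bootstrap interval 0.486 to 1.118) above that of all genes. A scaling factor applied to a whole library moves all genes nearly alike, so this distance could hardly change under any scaling. Its outcome was fixed in advance, and it is not counted as a test of scaling. The 4 other scalings all shift ratios upward and did not test whether the ratios themselves lie above 0. Length as the whole cause is argued against, since the distance was 0.509 (0.362 to 1.077) with the length trend removed. Whether more macrophages or dendritic cells account for part of it could not be decided. The interferon median minus the median of their markers was -0.062 (-0.207 to 0.713), an interval that spans 0. The median of the markers had itself an interval of -0.104 to 0.473. Like medians do not show that 1 list explains the other, so the explanation stays open. The genotype, or a difference between single animals, likewise stays open and untested.

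Mettl3 stood at a like level in both libraries. Loss of the transcript in most cells of the uterus was argued against, since the ratio of 0.963 (0.824 to 1.125) lay above 0.5. A loss confined to a minor cell type, a deletion that leaves most exons in the RNA, and a wrong label could each give the same value, and were not tested because values per exon were not used here. Directions in every paragraph therefore rest on the labels.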
